A study of Mus musculus with 26 samples.

How the data were processed

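Total RNA of mouse ES cells was profiled in 26 libraries, in 5 lines with replicates (24 libraries) and 1 line with 1 library before and 1 after 4-OHT. The authors deposited 1 table of FPKM values for 21110 features by gene symbol, with no symbol repeated and no read counts. Per the submitters' processing notes, reads were aligned with TopHat2 2.1.0 and quantified with Cufflinks 2.1.0 on mm9; the gene annotation and the options used are not given in the sources used here. Per the labels, libraries were sequenced on an Illumina HiSeq instrument. The labels' extraction protocol describes genomic DNA and a ChIP-seq library kit, although the molecule is given as total RNA, so whether the RNA was poly(A)-selected, depleted of ribosomal RNA or sequenced by strand is not known. Without strand, fragments of a gene and of an overlapping or antisense gene are not separable, and near-identical copies such as the Rhox2 genes may share fragments. The table held no feature named as of the mitochondrial genome. The rule for retroelements took Erv3 and, by its spelling, Iapp, a peptide hormone gene that was too low to be tested, so proviral families were not analysed here. No coordinates are given because the reference at hand was of another build than mm9. Symbols matched GENCODE M21 in 19109 cases and the RefSeq gene table in 18864.

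Every column was matched to its sample by the library code in the labels, and groups and replicate numbers were taken from the sample titles. Features at FPKM 1 or more in at least 2 of the 24 replicated libraries (13660) were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend; 1 coefficient per group, 14 residual degrees of freedom). Tests were two-sided and adjusted by Benjamini-Hochberg over all features of a comparison, and a feature was called at an adjusted p under 0.05. The 5 comparisons set each treated group against the untreated libraries of its line, and 6 differences of effects were tested between lines in the same fit. Baseline differences among the 5 untreated groups were tested together with limma's moderated F test. All these choices, the gene lists and the rule for named genes were fixed before the data were examined. By the same plan the Myc-Np95 line was described without a test, with the percentile of each list's median among 10000 random lists matched on mean expression; the 50 bins used for matching were not part of the plan.

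17 gene lists were fixed: germline genes methylated in somatic cells, the Rhox cluster, 2-cell stage, imprinted, pluripotency, trophectoderm and placenta, primitive endoderm, epiblast with mesoderm and ectoderm, interferon response, p53 target, proliferation, DNA methylation and H3K9 machinery, feeder fibroblast, replication-dependent histone, ribosomal protein, retroelement and mitochondrial genes. Lists with at least 5 tested members were compared with all other features by camera with a preset correlation of 0.01, adjusted over 75 tests for comparisons and 90 for differences. The retroelement list had 1 tested feature and the mitochondrial list none, so neither was tested. The same tests were repeated with the correlation estimated from the residuals. With it, the only list calls left in the 5 comparisons were the Rhox cluster in Np95 cKO and in DN cDKO. Overlaps are given beside the number expected of independent lists.

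The rule for named genes took the targeted genes and, per comparison, the 10 called features with the largest change each way whose treated libraries all lay beyond all untreated ones. It also took up to 4 members per list with the smallest p, 5 features each way per difference, and 10 each way in the Myc-Np95 line. Symbols of predicted or numbered genes were left out of the rule. 1 feature that the rule took is not reported here. 4933409K07Rik, Gm4262 and A430078G23Rik were therefore chosen after their values were seen. A feature listed at 0 in all libraries of a group is given without a fold, except for fitted differences between effects, which then depend on the pseudocount.

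Depth was estimated per library from the FPKM of weakly expressed features with a single annotated transcript, whose values cluster at the step of 1 fragment. Transcript lengths of GENCODE M21 were used, so the estimates are approximate. Replicate pairs were compared with the counting noise at these depths. In SN, untreated and treated libraries of the same replicate number, taken from the titles, correlated in their deviations from the group means (0.43, 0.35 and 0.48 for the 3 numbers). Each number is also 1 code range there, so pairing cannot be told apart from library series. The other lines have too few shared numbers to decide, at 0.85 in Np95, 0.51 in DN, 0.38 in SD and 0.59 and -0.01 in Dnmt1. Pairs of 1 code range correlated at 0.35 to 0.85 in every line, among them Dnmt1_wt 2 with Dnmt1_cKO 4 at 0.52. Fits with the replicate number as a block were planned as an alternative. In the Dnmt1 line that block pairs Dnmt1_wt 2 with Dnmt1_cKO 2, of another code range. Dnmt1_cKO 3 and 4 have no untreated partner in it and add nothing to its estimate of the effect.

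The procedure was tested on simulated values for 13660 features, normal around the untreated means with each feature's own spread, with 200 features changed. A log2 change of 1 was recovered in 27.5% of changed features in a layout like the Dnmt1 comparison, 15.0% in the Np95 layout and 37.0% in the SN layout. A log2 change of 2 was recovered in 88.5%, 77.5% and 82.0%, with 14, 6 and 8 false calls. At a log2 change of 1 the false calls were 2, 0 and 1 in the same order. With 2 libraries per group most 2-fold changes were thus missed, so a low count of calls in the Np95 line does not exclude them; the DN layout was not simulated.

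Alternatives planned before were a pseudocount of 0.1, no filter or a filter on mean FPKM of 1 or more, median-of-ratios scaling, the replicate block, the S059 series as a covariate, an added threshold of log2 change 1, only the compared groups in the fit, an estimated correlation and each library left out in turn. Added after the data had been seen were code range as a block, close pairs averaged, the 3 shallowest libraries left out, Dnmt1_cKO 2 and 3 left out, and small RNA features (152 tested) left out. For repeated sequence, 31-mers at every 10 bases of each feature's longest GENCODE M21 transcript were searched in the transcripts of other genes. A 31-mer in at least 10 other genes counted as repeated. Medians were set against 10000 random sets of as many features. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9 were used besides R.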

Results

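RNA was sequenced from 26 libraries of mouse embryonic stem (ES) cells, the cultured cells of the early embryo that can form all its tissues. Each line carried floxed alleles of 1 or 2 genes and CreERT2, a Cre recombinase that 4-hydroxytamoxifen (4-OHT) sends into the nucleus, where it removes the floxed segments. Untreated cells (day 0, called wt in the labels) were compared with cells of the same line at day 6 of 4-OHT, called cKO for 1 targeted gene and cDKO for 2. The genes were Dnmt1, the enzyme that copies DNA methylation onto the new strand after replication; Np95 (symbol Uhrf1), which binds hemimethylated DNA and recruits DNMT1; and Setdb1, a histone H3 lysine 9 methyltransferase that silences proviruses. The groups were Dnmt1 (2 untreated and 4 treated libraries), Np95 (2 and 2), Dnmt1 with Np95 (DN, 2 and 2), Setdb1 with Np95 (SN, 3 and 3), Setdb1 with Dnmt1 (SD, 2 and 2), and a DN line carrying Myc-tagged NP95 (1 and 1). Every line had its own untreated libraries, so exposure to 4-OHT and Cre is part of every comparison, and differences between lines are also differences between clones. A line with Setdb1 deleted alone was not analysed here.

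The deposited table gives 21110 features in FPKM (fragments per kilobase of transcript, scaled to the depth of the library) and no read counts, so depth was estimated from the spacing of the lowest FPKM values. Estimated depth, in megafragments, was 1.79 in SN_wt 1, 2.21 in SN_cDKO 1 and 3.02 in Dnmt1_cKO 2. It was 10.5 to 30.8 in the other 23 libraries. At those depths 1 fragment on a transcript of 2 kb corresponds to 0.279 FPKM in SN_wt 1 and 0.0162 FPKM in Dnmt1_wt 1, so values near these steps carry little precision. The sum of FPKM over all features ranged from 359394 in SD_cDKO 2 to 716569 in DN_cDKO 1. The library codes in the labels fall into 6 ranges, and the last replicate of every replicated group has a code starting with S059. Group accounted for 53.7% of the variance of the log2 values of the 24 replicated libraries, group with the S059 series for 70.7%, and code range alone for 45.8%, so medians of gene lists are also given for the S059 libraries and the other libraries apart. Nothing in the labels says that replicates came from separate cultures, and p-values therefore measure the spread between these libraries, which may in part be technical. Of 19 replicate pairs within groups, 3 were far closer than the rest (SN_wt 1 and 2, SN_cDKO 1 and 2, Dnmt1_cKO 2 and 3). Their variance was 2.13 to 4.76 times the counting noise, against 17.7 to 106 times in the other 16 pairs. The counting noise rests on approximate depths and transcript lengths, so these ratios cannot tell whether the 3 pairs are repeat runs of 1 culture. The pairs were kept as separate libraries, but if they are repeat runs of 1 culture the p-values below are too small.

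The first question was whether each targeted transcript fell in its own line. Dnmt1 fell in the Dnmt1 line from 70.4 ± 24.5 FPKM (mean ± SD, n = 2) to 7.53 ± 1.85 (n = 4), a log2 change of -3.05 (SE 0.243; limma, Benjamini-Hochberg adjusted p = 7.78e-06). Uhrf1 fell in the Np95 line from 100.2 ± 6.34 FPKM to 12.3 ± 0.921 (n = 2 and 2; log2 change -2.93, adjusted p = 2.82e-04), where Dnmt1 stood at 53.4 and 58.4 FPKM. In the DN line both fell, Dnmt1 from 53.9 ± 4.44 to 8.75 ± 0.107 FPKM (log2 change -2.49, adjusted p = 6.25e-04) and Uhrf1 from 63.6 ± 3.53 to 10.9 ± 0.453 FPKM (log2 change -2.44, adjusted p = 0.00122). In the SN line Uhrf1 fell from 92.4 ± 4.79 to 7.83 ± 1.28 FPKM (n = 3 and 3; log2 change -3.41, adjusted p = 1.34e-07) and Setdb1 from 23.1 ± 3.45 to 6.19 ± 2.15 FPKM (log2 change -1.78, adjusted p = 1.2e-05). In the SD line Dnmt1 fell from 51 ± 1.25 to 5.16 ± 0.204 FPKM (log2 change -3.08, adjusted p = 2.25e-06) and Setdb1 from 22.5 ± 2.65 to 3.32 ± 0.893 FPKM (log2 change -2.45, adjusted p = 5.01e-06). Uhrf1, which was not targeted in the SD line, fell there as well, from 87.6 ± 3.23 to 32.1 ± 1.14 FPKM (log2 change -1.42, adjusted p = 0.00203). Dnmt1 in the SN line was 43.2 ± 5.53 and 37.6 ± 10.9 FPKM (adjusted p = 0.488). Uhrf1 in the Dnmt1 line was 108 ± 27.6 and 88.9 ± 34.5 FPKM (log2 change -0.34, adjusted p = 0.55), a direction that turned (log2 change 0.15) without Dnmt1_cKO 2 and 3. When only the libraries of a line entered its fit, the targeted genes of the Dnmt1, Np95, DN and SD lines no longer passed (adjusted p = 0.0558 for Dnmt1 in SD to 0.545 for Uhrf1 in Np95).

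**Figure D1:**
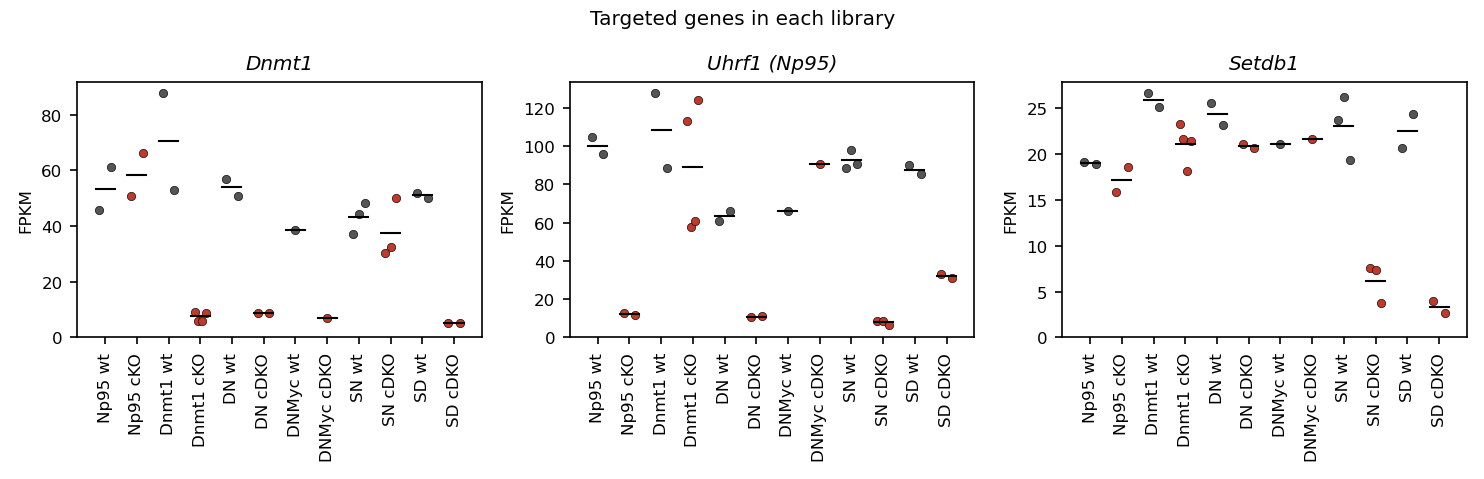
FPKM of Dnmt1, Uhrf1 (Np95) and Setdb1 in each of the 26 libraries (points; grey untreated, red at day 6 of 4-OHT), with the group mean as a line. In the 5 replicated lines each targeted gene lies lower in every treated library than in every untreated library of its own line, for example Dnmt1 at 5.01 to 5.30 FPKM in SD cDKO.

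In Dnmt1 cKO, with Dnmt1 alone targeted, a small set of genes rose, among them germline and Rhox genes, and fewer fell. Zfp575, a zinc-finger gene, rose from 1.68 ± 0.880 FPKM (n = 2) to 61.1 ± 48.6 (n = 4), and Cox7b2, a testis subunit of cytochrome c oxidase, rose from 0.389 ± 0.0520 to 14.9 ± 7.47 FPKM. Asz1, needed for piRNA production in germ cells, rose from 0.0408 ± 0.0309 to 2.17 ± 0.463 FPKM, and Taf7l, a germ-cell transcription factor subunit, from 0.733 ± 0.0631 to 8.31 ± 2.72 FPKM. Ddit4, a stress-induced inhibitor of mTOR, fell from 276 ± 26.2 to 129 ± 15.1 FPKM, and Lss, an enzyme of cholesterol synthesis, fell from 30.9 ± 0.540 to 15.0 ± 1.41 FPKM. By limma with Benjamini-Hochberg adjustment, 51 of 13660 features changed, 41 higher and 10 lower. All had the same direction in the S059 libraries and in the others, but they were called on both sets together. That agreement is therefore no separate check. Over all features the log2 changes of these 2 sets correlated at 0.22. Log2 changes of the other named genes that rose were 3.41 for Rpl39l, 2.71 for Serpinb6b, 2.54 for H2-Eb1 (an MHC class II chain), 2.35 for Pnma5, 2.26 for Xlr4c and 2.08 for Pros1. Rgl3 (-1.53), Arrdc2 (-1.17), Phyhip (-1.02) and Sv2a (-0.97) fell.

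Among 33 germline genes that are methylated in somatic cells, Asz1, Taf7l and Gtsf1 (log2 changes 1.60, 2.37 and 1.82) rose in Dnmt1 cKO and the other 30 did not pass; 13 rose and 1 fell when adjusted over the list alone. The list's median was 0.75 (0.80 in the S059 libraries, 0.45 in the others) and camera called it higher (adjusted p = 8.5e-07), but not with an estimated correlation (adjusted p = 0.345 with an estimated correlation). Of 20 genes of the Rhox cluster, X-linked homeobox genes of the germline and placenta, Rhox1 (2.11), Rhox2a (1.14) and Rhox2e (0.97) rose, and 6 rose adjusted over the list alone. The Rhox median was 0.55 (0.76 and 0.49). For the Rhox cluster camera gave an adjusted p of 1.02e-08, and adjusted p = 0.184 with an estimated correlation. None of 27 primitive endoderm genes passed over all features, though 14 rose adjusted over the list alone, with a median of 1.86 (1.20 and 1.77). For the primitive endoderm list camera gave an adjusted p of 1.68e-10, and adjusted p = 0.352 with an estimated correlation. Sparc, a matrix protein, stood at 219 ± 52.9 and 1709 ± 1431 FPKM, and Col4a1 and Gata6 had log2 values of 2.58 and 2.22 (adjusted p = 0.14 and 0.197). Feeder fibroblast markers, which would report carry-over of feeder cells, had a median of 1.12 with 0 of 37 called (0 adjusted over the list alone; -0.38 in the S059 libraries, 1.31 in the others); Ctgf and Cyr61 had log2 values of 1.78 and 1.71. For the feeder list camera gave an adjusted p of 0.0143, and adjusted p = 0.823 with an estimated correlation. With the replicate block 2 of these 37 rose (camera adjusted p = 1.2e-09).

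Plk2 (1.56) was the 1 of 34 p53 target genes that rose in Dnmt1 cKO (7 adjusted over the list alone; median 0.46, 0.52 and 0.47), a call lost with median-of-ratios scaling, with the replicate block and in 4 of 6 fits with 1 library left out. With the replicate block 2 members of the p53 list rose. For the p53 list camera gave an adjusted p of 5.88e-05, and adjusted p = 0.345 with an estimated correlation. None of 17 genes of the 2-cell stage passed (median 0.52, 0.69 and 0.44), and Zscan4c stood at 0.712 and 4.15 FPKM. For the 2-cell list camera gave an adjusted p of 0.00126, and adjusted p = 0.454 with an estimated correlation. None of 53 imprinted genes passed, 8 rose adjusted over the list alone, and the median was 0.11 (0.16 and 0.17). With the replicate block 4 rose over all features. Xlr3b and Xlr4b had log2 values of 3.00 and 2.27. For the imprinted list camera gave an adjusted p of 0.0485, and adjusted p = 0.345 with an estimated correlation. Replication-dependent histone genes had a median of -0.84 with 0 of 52 called (0.00 in the S059 libraries, -0.86 in the others). For the histone list camera gave an adjusted p of 3.66e-05, and adjusted p = 0.587 with an estimated correlation. Ribosomal protein genes had a median of -0.32 (-0.20 and -0.33), and the 1 that rose of 51, Rpl39l, is a testis-enriched copy. For the ribosomal list camera gave an adjusted p of 0.00415, and adjusted p = 0.587 with an estimated correlation. Proliferation genes and the DNA methylation and H3K9 machinery had medians of -0.21 and -0.22 with no member called (camera adjusted p = 0.00415 and 0.0172, adjusted p = 0.535 and 0.454 with an estimated correlation). The pluripotency, trophectoderm, epiblast and interferon lists were not called (medians -0.17, 0.11, -0.06 and 0.09). Erv3, the only tested feature of the list of retroelements, was 0.104 and 0.587 FPKM (adjusted p = 0.238). The count of 51 moved with single libraries, to 7 and 5 without Dnmt1_wt 1 or 2 and to 175, 23, 17 and 207 without Dnmt1_cKO 1, 2, 3 or 4. With close pairs averaged it was 9, where of the named genes above only Dnmt1, Zfp575, Cox7b2, Asz1 and Rhox2e still passed (adjusted p = 0.0834 for Taf7l, 0.1 for Gtsf1, 0.0579 for Rhox1 and 0.104 for Rhox2a). It was 8 without the 3 shallowest libraries, 17 without Dnmt1_cKO 2 and 3, and 0 with only these 6 libraries in the fit.

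Deletion of Np95 alone changed 5 features, the fall of Uhrf1 and the rise of 4 neighbouring Rhox2 copies. Rhox2a rose from 0.512 ± 0.310 to 3.46 ± 0.771 FPKM (n = 2 and 2; log2 change 1.57, adjusted p = 0.0168), Rhox2e from 0.256 ± 0.0697 to 2.07 ± 0.162 FPKM (1.29, adjusted p = 0.0127), Rhox2c by 1.19 and Rhox2b by 1.13 (limma). These copies are near-identical, so fragments may be split between them and the single values are uncertain. None of the 4 passed with the replicate block. All 20 tested Rhox genes lay above 0, 13 of them rose adjusted over the list alone, and the median was 0.96 (1.14 in the S059 libraries, 0.87 in the others). For the Rhox cluster camera gave an adjusted p of 4.8e-43, and adjusted p = 0.00257 with an estimated correlation. Germline genes had a median of 0.49 with 0 of 33 called and 3 adjusted over the list alone (0.51 and 0.46). For the germline list camera gave an adjusted p of 1.43e-13, and adjusted p = 0.127 with an estimated correlation. Dazl, an RNA-binding protein of germ cells, stood at 8.97 ± 5.23 and 51.5 ± 28.6 FPKM, Asz1 at 0.117 and 1.64 FPKM (adjusted p = 0.0963) and Gtsf1 at 1.80 and 8.06 FPKM (adjusted p = 0.283). Feeder, interferon, ribosomal and histone lists had medians of -0.42, -0.06, -0.19 and -0.08 and p53 targets 0.19, each called by camera with no member called (adjusted p = 0.748, 0.454, 0.454, 0.753 and 0.587 with an estimated correlation). Pluripotency genes had a median of 0.04, which turned to -0.02 with median-of-ratios scaling, and 2-cell genes -0.09, neither called. At an unadjusted p under 0.05 there were 190 features. The count of 5 became 2, 1, 2 and 1 without Np95_wt 1, Np95_wt 2, Np95_cKO 1 or Np95_cKO 2, 1 with the replicate block and 0 with only these 4 libraries in the fit.

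Deletion of Dnmt1 and Np95 together (DN) changed 4 features by limma, the fall of both targets and the rise of Plcd4 and Snord91a. Plcd4, a phospholipase C, rose from 0.506 ± 0.110 to 2.56 ± 0.141 FPKM (n = 2 and 2; log2 change 1.24, adjusted p = 0.00594), a call lost in 3 of 4 fits with 1 library left out and with the replicate block. Snord91a, a small nucleolar RNA, was listed at 0 in both untreated libraries and at 459 ± 38.4 FPKM in DN cDKO. The FPKM of such short transcripts rests on few fragments. All 20 Rhox genes lay above 0, with 0 called and 6 adjusted over the list alone, and the median was 0.75 (0.83 in the S059 libraries, 0.66 in the others). For the Rhox cluster camera gave an adjusted p of 3.93e-34, and adjusted p = 0.00427 with an estimated correlation. Rhox2b had a log2 value of 0.88 (adjusted p = 0.116) and Rhox2a of 1.03 (0.74). The germline list had a median of 0.29 (0.39 and 0.32) with 0 of 33 called; Asz1 had a log2 value of 0.85 and Dazl of 1.92. For the germline list camera gave an adjusted p of 2.96e-07, and adjusted p = 0.345 with an estimated correlation. The p53 target list had a median of 0.34 (0.41 and 0.27), with Mdm2, the ubiquitin ligase that p53 induces, at 44.6 and 74.7 FPKM. For the p53 list camera gave an adjusted p of 4.81e-10, and adjusted p = 0.127 with an estimated correlation. Genes of the 2-cell stage had a median of -0.19 (0.20 and -0.61) and feeder markers -0.32 (adjusted p = 0.862 with an estimated correlation). For the 2-cell list camera gave an adjusted p of 6.24e-04, and adjusted p = 0.454 with an estimated correlation. At an unadjusted p under 0.05 there were 154 features. The count of 4 was 3 with only these 4 libraries in the fit. Neither Dnmt1 nor Uhrf1 passed there (limma adjusted p = 0.0933 for both), so the 3 are not all among the 4.

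Deletion of Setdb1 with Np95 (SN) changed 4202 features. Among them 25 of 41 pluripotency genes fell and 15 of 17 genes of the 2-cell stage, 14 of 28 of the trophectoderm and 19 of 38 of the interferon response rose. None of these lists was called with an estimated correlation (adjusted p = 0.352, 0.127, 0.345 and 0.345), and the interferon median was 0.12 in the S059 libraries and 1.54 in the others, where feeder markers stood at 0.34 and 2.51. Cd209c, a C-type lectin, rose from 1.83 ± 0.623 to 849 ± 254 FPKM (n = 3 and 3; log2 change 8.22, adjusted p = 8.31e-08), Rbmy1a1, a testis RNA-binding protein, from 0.0899 ± 0.0274 to 193 ± 33.2 FPKM, and Zfp575 from 1.27 ± 0.314 to 376 ± 54.4 FPKM. Nanog and Sox2, transcription factors of pluripotent cells, fell from 255 ± 87.3 to 32.7 ± 16.3 FPKM and from 271 ± 68.3 to 31.1 ± 6.73 FPKM. Fgf4 fell from 122 ± 25.1 to 10.5 ± 5.81 FPKM. By limma 1844 features were higher and 2358 lower. Of the 4202, 4147 (98.7%) had the same direction in the S059 libraries and in the others (correlation over all features 0.60). They were called on both sets together, so their shared direction is no separate check. The median of all features was -0.09 and moved by 0.12 with median-of-ratios scaling, where 2319 were higher and 1825 lower. Other large log2 changes were 6.51 for Psg23 (a placental glycoprotein), 5.89 for Tex101 (a germ-cell membrane protein), 5.30 for Bckdhb (28.1 to 1155 FPKM), 4.82 for Nxf7 and 4.77 for Serpinb1c. Ndufa4l2 (-3.92), Olig1 (-3.64), Lrrc34 (-3.61), Tdgf1 (-3.45, an epiblast growth factor co-receptor), Aldoc (-3.45) and Ifitm1 (-3.42) fell as well.

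In SN cDKO 25 of 41 pluripotency genes fell and 1 rose (28 and 1 adjusted over the list alone), with a median of -1.45 (-2.02 in the S059 libraries, -1.06 in the others), where ribosomal protein genes, a list fixed as a sign of RNA quality, stood at -1.12 and -0.31; Tcl1 fell by 3.31 on the log2 scale. For the pluripotency list camera gave an adjusted p of 1.21e-07, and adjusted p = 0.352 with an estimated correlation. Of 38 proliferation genes 26 fell and 1 rose (29 and 1 adjusted over the list alone; median -0.94, -1.06 and -0.84), among them Pcna, the replication clamp (323 ± 21.8 to 145 ± 20.6 FPKM), Aurkb (-1.58) and Bub1b (-1.52). For the proliferation list camera gave an adjusted p of 4.81e-10, and adjusted p = 0.213 with an estimated correlation. Genes of the 2-cell stage, active when the embryo's genome switches on, rose in 15 of 17 cases (15 adjusted over the list alone), with a median of 1.92 (2.12 and 2.01). For the 2-cell list camera gave an adjusted p of 1.51e-12, and adjusted p = 0.127 with an estimated correlation. Dub1 rose from 0.482 ± 0.0379 to 6.90 ± 0.173 FPKM, Zfp352 by 1.91, Tdpoz3 by 1.92 and Arg2 by 1.90. Germline genes rose in 14 of 33 cases and 1 fell (15 and 1 adjusted over the list alone; median 0.77, 1.28 and 0.80), with Taf7l at 3.87, Stk31 at 2.56 and Gtsf1 at 2.47. For the germline list camera gave an adjusted p of 2.91e-06, and adjusted p = 0.352 with an estimated correlation. Of 20 Rhox genes 10 rose (12 adjusted over the list alone; median 0.78, 1.45 and 0.32), led by Rhox6 (9.99 ± 11.5 to 244 ± 323 FPKM) and Rhox13 (2.56). For the Rhox cluster camera gave an adjusted p of 3.66e-05, and adjusted p = 0.345 with an estimated correlation. Imprinted genes rose in 14 of 53 cases and 2 fell (16 and 2 adjusted over the list alone; median 0.41, 0.36 and 0.39); H19, a maternally expressed RNA, rose from 62.0 ± 34.8 to 1727 ± 2041 FPKM and Osbpl5 rose by 1.69. For the imprinted list camera gave an adjusted p of 9.45e-04, and adjusted p = 0.127 with an estimated correlation.

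Markers of extraembryonic lineages rose as well in SN cDKO. Of 28 trophectoderm and placenta genes 14 rose and 0 fell (18 adjusted over the list alone; median 1.5, 2.49 in the S059 libraries and 1.11 in the others). For the trophectoderm list camera gave an adjusted p of 1.21e-07, and adjusted p = 0.345 with an estimated correlation. The keratin genes Krt8 (20.9 ± 27.5 to 898 ± 1064 FPKM) and Krt18 (33.6 ± 33.2 to 954 ± 956 FPKM) rose, with Ldoc1 at 3.55 and Lgals3 at 3.48. Of 27 primitive endoderm genes 12 rose (14 rose and 1 fell adjusted over the list alone), with Col4a2 at 3.29 and Col4a1 at 3.41, and the median was 1.82, but 0.09 in the S059 libraries and 2.51 in the others. For the primitive endoderm list camera gave an adjusted p of 2.59e-05, and adjusted p = 0.506 with an estimated correlation. Interferon response genes rose in 19 of 38 cases and 3 fell (20 and 3 adjusted over the list alone; median 1.13, 0.12 and 1.54). For the interferon list camera gave an adjusted p of 8.06e-07, and adjusted p = 0.345 with an estimated correlation. Isg15, a ubiquitin-like protein induced by interferon, rose from 0.631 ± 0.986 to 40.0 ± 23.6 FPKM, Irf7 by 2.40, Usp18 by 2.30 and Tap1, a peptide transporter for MHC class I, by 1.79. Feeder fibroblast markers followed the same division of libraries: 5 of 37 rose (2 adjusted over the list alone) with a median of 1.85, 0.34 in the S059 libraries and 2.51 in the others, among them Lum (1.64), Pdgfrb (1.90), Ccl2 (3.81) and Cyr61 (1.96). For the feeder list camera gave an adjusted p of 1.32e-04, and adjusted p = 0.69 with an estimated correlation. With the replicate block 25 of these 37 rose.

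Smaller shifts in SN cDKO concerned p53 targets, of which 9 of 34 rose and 4 fell (11 and 4 adjusted over the list alone; median 0.31, 0.49 and 0.08), with Phlda3 at 1.23, Btg2 at 1.24 and Plk2 at 1.56. For the p53 list camera gave an adjusted p of 0.017, and adjusted p = 0.506 with an estimated correlation. Of 43 genes of the DNA methylation and H3K9 machinery 14 fell and 3 rose (14 and 6 adjusted over the list alone; median -0.30, camera adjusted p = 0.0858). The 5-methylcytosine oxidases Tet1 and Tet2 fell by 2.18 and 2.11 on the log2 scale and Zfp57, which protects imprints, fell by 1.81, while Zfp809, a zinc-finger protein that recruits silencing to proviruses, rose by 1.49. Ribosomal protein genes had a median of -0.57 (-1.12 and -0.31; 4 of 51 fell and 1 rose, 2 and 1 adjusted over the list alone, 11 and 1 with the replicate block); Rpl22l1 fell by 1.34 and Rpl39l rose by 4.00. For the ribosomal list camera gave an adjusted p of 0.0107, and adjusted p = 0.619 with an estimated correlation. Of 52 histone genes 5 rose (3 adjusted over the list alone, 10 with the replicate block), with Hist1h2bc at 2.26 and Hist1h1c at 2.05, and the list was not called (median -0.10). Of 20 epiblast, mesoderm and ectoderm genes 3 rose (3 adjusted over the list alone), with Msx2 at 2.73 (median 0.47). For the epiblast list camera gave an adjusted p of 0.0416, and adjusted p = 0.454 with an estimated correlation; with median-of-ratios scaling it was 0.0989. Erv3 rose from 0.155 ± 0.0666 to 0.881 ± 0.291 FPKM. The count of 4202 was 6775 with code range as a block, 2334 with close pairs averaged, 2485 without the 3 shallowest libraries and 2435 with only these 6 libraries in the fit. With close pairs averaged Lum, Pdgfrb, Ccl2, Cyr61 and Erv3 no longer passed (adjusted p = 0.101, 0.0863, 0.187, 0.13 and 0.0622).

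**Figure D2:**
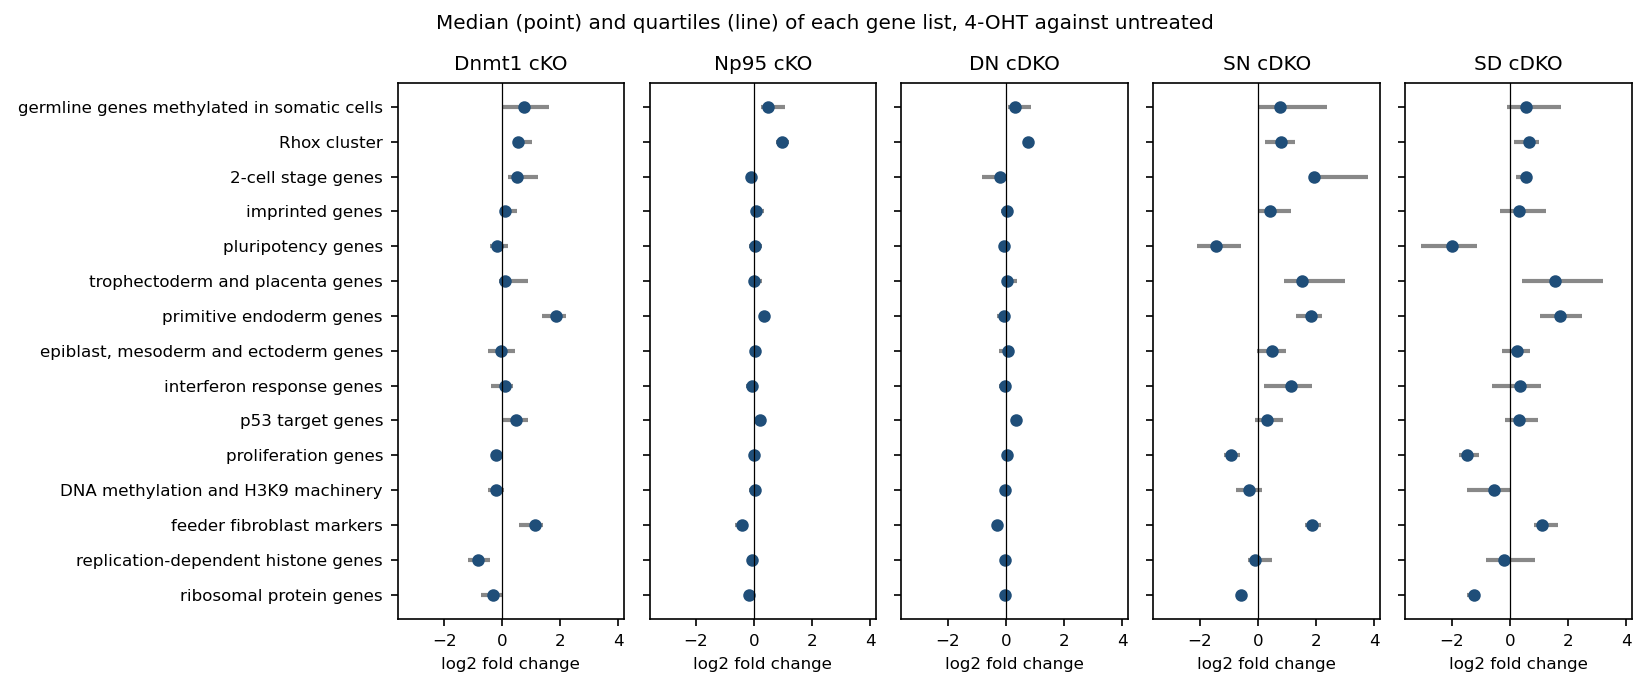
Median (point) and quartiles (line) of the log2 fold change of each gene list, 4-OHT against untreated, in 1 panel per line. Pluripotency genes lie near 0 in Np95 cKO and DN cDKO (medians 0.04 and -0.06; the first turns to -0.02 with median-of-ratios scaling) and at -1.45 and -1.99 in SN cDKO and SD cDKO.

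Deletion of Setdb1 with Dnmt1 (SD) changed 4218 features. Among them 27 of 41 pluripotency and 36 of 38 proliferation genes fell and 12 of 28 trophectoderm genes rose, lists that were not called with an estimated correlation (adjusted p = 0.352, 0.127 and 0.345). Cd209c rose from 2.52 ± 0.997 to 894 ± 204 FPKM (n = 2 and 2; log2 change 8.0, adjusted p = 1.49e-06), Zfp575 from 2.25 ± 0.460 to 783 ± 511 FPKM and Bckdhb, a subunit of branched-chain ketoacid dehydrogenase, from 27.6 ± 7.26 to 1574 ± 675 FPKM. Nanog fell from 196 ± 61.0 to 8.62 ± 6.28 FPKM, Sox2 from 258 ± 16 to 13.6 ± 7.50 FPKM and Fgf4 from 111 ± 37.4 to 2.92 ± 2.40 FPKM. Krt8 rose from 71.1 ± 86.1 to 1772 ± 1163 FPKM and Clu, a secreted chaperone, from 27.0 ± 24.6 to 798 ± 292 FPKM. By limma 1359 features were higher and 2859 lower. Of the 4218, 4216 had the same direction in the S059 libraries and in the others (correlation over all features 0.65). Here too the features were called on both sets together, so their shared direction is no separate check. The median of all features was -0.23 and moved by 0.26 with median-of-ratios scaling, where 2168 were higher and 1910 lower, so the excess of falls depends on the scale of the FPKM. Further log2 changes were 6.68 for Psg23, 5.58 for Vnn1, 5.44 for Rbmy1a1 and 5.19 for Serpinb1c, and -5.71 for Ifitm1 (291 to 6.40 FPKM), -5.38 for Trh, -4.51 for Tdgf1 and -4.17 for Ndufa4l2. The small RNAs Mir130b and Mir877 were listed at 0 in both treated libraries and at 81.5 ± 18.5 and 67.6 ± 14.9 FPKM in the untreated ones. Mir130b was also listed at 0 in every library of the Dnmt1, Np95, DN and SN lines, treated or untreated. For Mir130b the untreated SD libraries are thus the ones that stand apart.

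In SD cDKO 27 of 41 pluripotency genes fell and 1 rose (31 and 1 adjusted over the list alone), with a median of -1.99 (-2.44 in the S059 libraries, -1.70 in the others), where ribosomal protein genes stood at -1.69 and -0.77; Tcl1 fell by 3.99 on the log2 scale. For the pluripotency list camera gave an adjusted p of 7.31e-08, and adjusted p = 0.352 with an estimated correlation. Of 38 proliferation genes 36 fell and 1 rose (37 and 1 adjusted over the list alone; median -1.47, -1.64 and -1.22), with Pcna at -1.69, Aurkb at -2.27, Cenpa at -2.26 and Rrm2 at -1.75. For the proliferation list camera gave an adjusted p of 1.56e-13, and adjusted p = 0.127 with an estimated correlation. Of 28 trophectoderm and placenta genes 12 rose (13 adjusted over the list alone; median 1.55, 1.99 and 1.13), with Krt18 at 4.25, Lgals3 at 4.10 and Krt19 at 3.68. For the trophectoderm list camera gave an adjusted p of 2.08e-07, and adjusted p = 0.345 with an estimated correlation. Of 27 primitive endoderm genes 10 rose (11 rose and 1 fell adjusted over the list alone), with Col4a2 at 3.73, Lama1 at 3.64 and Lamc1 at 2.45, and the median of 1.73 was 0.13 in the S059 libraries and 3.52 in the others. For the primitive endoderm list camera gave an adjusted p of 2.64e-06, and adjusted p = 0.454 with an estimated correlation. Feeder markers had a median of 1.11 (0.62 and 1.51), and 1 of 37, Cyr61 (2.09, adjusted p = 0.0471), rose (0 adjusted over the list alone, 11 of 37 over all features with the replicate block). The call of Cyr61 was lost in all 4 fits with 1 library left out and with close pairs averaged (adjusted p = 0.0652). For the feeder list camera gave an adjusted p of 0.00128, and adjusted p = 0.762 with an estimated correlation. Germline genes rose in 10 of 33 cases and 1 fell (10 and 1 adjusted over the list alone; median 0.56, 0.71 and 0.45), with Tex101 at 4.94, Taf7l at 4.43 and Gtsf1 at 2.46. For the germline list camera gave an adjusted p of 5.53e-05, and adjusted p = 0.442 with an estimated correlation. Of 20 Rhox genes 6 rose (6 adjusted over the list alone; median 0.66, 0.89 and 0.48), with Rhox6 at 4.16 and Rhox13 at 3.42. For the Rhox cluster camera gave an adjusted p of 1.17e-04, and adjusted p = 0.352 with an estimated correlation. Of 17 genes of the 2-cell stage Dub1 (0.96, adjusted p = 0.0497; lost in 2 of 4 fits with 1 library left out) rose (0 adjusted over the list alone), and the median of 0.57 was 1.52 in the S059 libraries and -0.47 in the others. For the 2-cell list camera gave an adjusted p of 0.0236, and adjusted p = 0.619 with an estimated correlation.

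Interferon response genes went both ways in SD cDKO, 7 of 38 rose and 6 fell (7 and 6 adjusted over the list alone; median 0.35, 0.04 and 0.24; camera adjusted p = 0.117), with Tap1 at 1.61, Stat2 at -1.61 and Oas3 at -1.16. Imprinted genes rose in 9 of 53 cases and 4 fell (9 and 2 adjusted over the list alone, 18 and 4 with the replicate block; median 0.31, 0.25 and 0.45), with Osbpl5 at 1.82 and Ndn at 1.52. For the imprinted list camera gave an adjusted p of 0.00214, and adjusted p = 0.127 with an estimated correlation. Of 34 p53 targets 8 rose and 3 fell (8 and 3 adjusted over the list alone; median 0.33, 0.14 and 0.33), with Perp at 2.13 and Phlda3 at 1.33. For the p53 list camera gave an adjusted p of 0.00687, and adjusted p = 0.454 with an estimated correlation. Of 43 machinery genes 18 fell and 3 rose (20 and 3 adjusted over the list alone; median -0.54, -0.85 and -0.51); Cbx1, an HP1 protein, fell by 2.11 on the log2 scale, Hells, a chromatin remodeller, by 1.81 and Zfp57 by 2.49. For the machinery list camera gave an adjusted p of 0.017, and adjusted p = 0.454 with an estimated correlation. Of 51 ribosomal protein genes 21 fell and 1 rose (25 and 1 adjusted over the list alone, 12 falls with median-of-ratios scaling and 36 with the replicate block; median -1.22, -1.69 and -0.77), with Rpl22 at -1.75 and Rpl3 at -1.56. For the ribosomal list camera gave an adjusted p of 7.36e-05, and adjusted p = 0.454 with an estimated correlation. Of 52 histone genes 5 rose (3 adjusted over the list alone, 11 with the replicate block), Hist1h1c by 2.62; the list's median was -0.22, turned to 0.06 with median-of-ratios scaling, and camera called the list higher (adjusted p = 0.0293, adjusted p = 0.823 with an estimated correlation, adjusted p = 0.187 with scaling). Of 20 epiblast, mesoderm and ectoderm genes 3 rose (1 adjusted over the list alone), with Msx2 at 2.82, and the list was not called (median 0.25). Erv3 rose from 0.101 ± 0.0863 to 0.729 ± 0.417 FPKM (adjusted p = 0.0267), a call lost in 3 of 4 fits with 1 library left out and with only these 4 libraries in the fit (adjusted p = 0.191). The count of 4218 was 2407 without SD_wt 1, 2600 without SD_cDKO 2, 6822 with code range as a block and 26 with only these 4 libraries in the fit. In that last fit Nanog, Sox2 and Fgf4 did not pass (adjusted p = 0.0724 each).

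**Figure D3:**
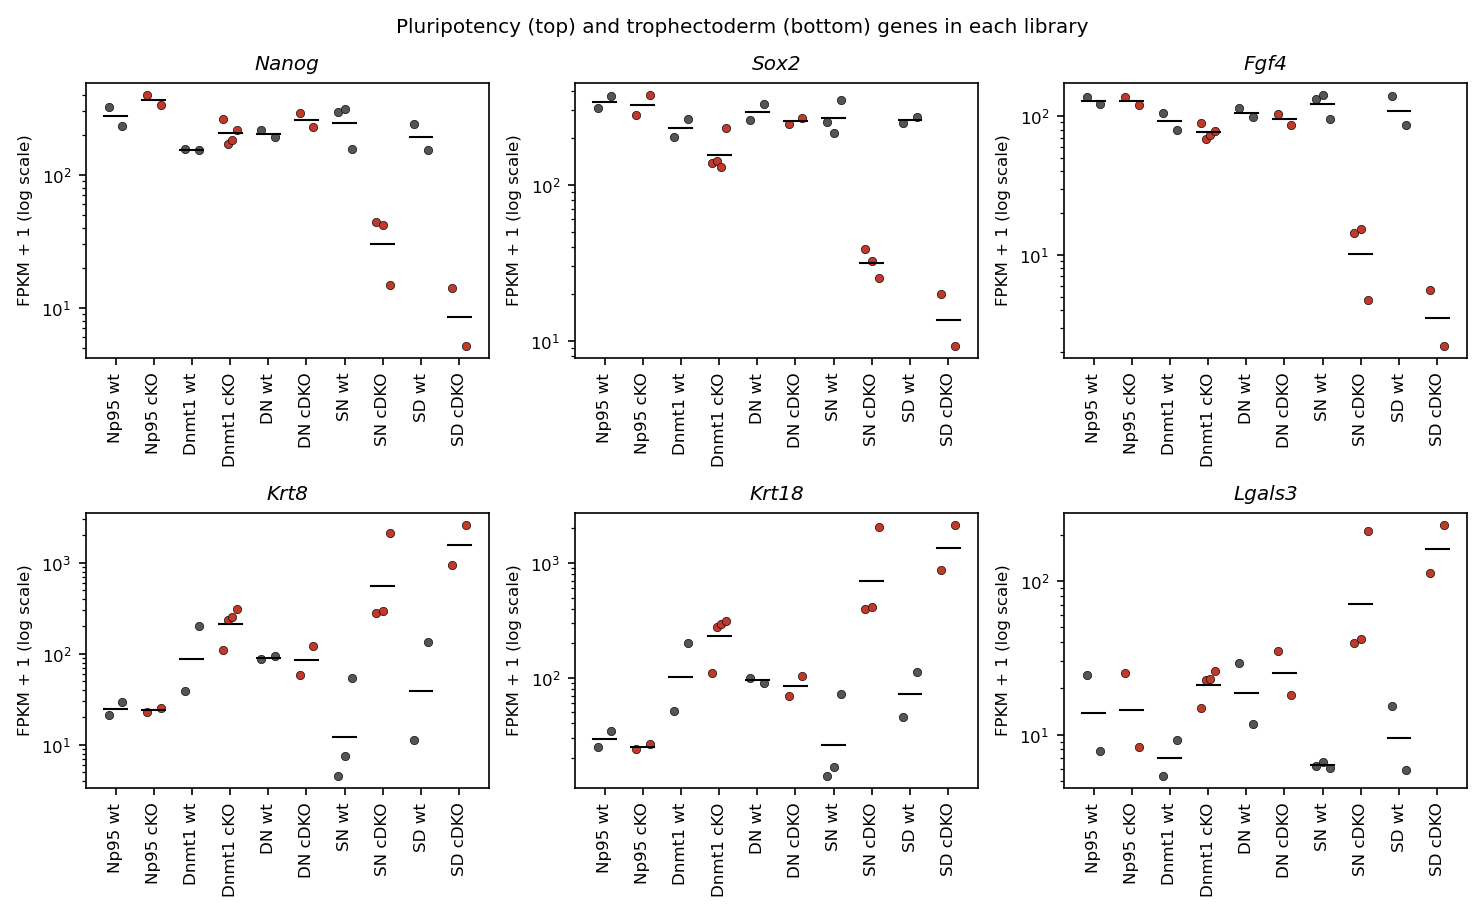
FPKM + 1 on a log scale of 3 pluripotency genes (Nanog, Sox2, Fgf4) and 3 trophectoderm genes (Krt8, Krt18, Lgals3) in each of the 24 replicated libraries (points; grey untreated, red at day 6 of 4-OHT), with the geometric mean of each group as a line. The pluripotency genes lie lowest in SN cDKO and SD cDKO, where mean Nanog was 32.7 and 8.62 FPKM.

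Whether the same genes moved in different lines was asked next. SN cDKO and SD cDKO, which have separate untreated libraries, shared 1097 features that rose, against 183 for independent lists, and 1963 that fell, against 494. Their log2 changes correlated across the 13660 features with Pearson's r of 0.83 and Spearman's rho of 0.88, and genes are not independent replicates. The 41 features that rose in Dnmt1 cKO had a median of 1.71 there. In Np95 cKO their median was 0.55 (40 of 41 above 0, adjusted p = 5.78e-05 with an estimated correlation), in DN cDKO 0.69 (40 of 41, adjusted p = 2.13e-05), in SN cDKO 1.31 (38 of 41, 26 of them called, adjusted p = 0.0031) and in SD cDKO 1.43 (34 of 41, 25 called, adjusted p = 0.00312). The 9 features that fell besides Dnmt1 itself had medians of -0.34, -0.24, -1.33 and -1.69 in the same order. With 1 library left out the Np95 value ran from -0.60 to -0.08 and the DN value from -0.31 to -0.13, and the DN median of the 41 from 0.40 to 0.97. Of the 1097 features higher in both SN and SD cDKO, 992 lay above 0 in Dnmt1 cKO (median 0.44, adjusted p = 0.0123 with an estimated correlation), where the medians in Np95 cKO and DN cDKO were 0.10 and 0.05 (adjusted p = 0.278 for both). Their effect in Dnmt1 cKO exceeded that in DN cDKO by a median of 0.34 (922 of 1097 above 0, adjusted p = 0.0154 with an estimated correlation) and that in Np95 cKO by 0.31 (adjusted p = 0.019). Over the DN effect the excess was 0.09 in the S059 libraries and 0.54 in the others, where feeder markers differed by 0.06 and 1.53 and primitive endoderm genes by 0.35 and 2.84. The 1961 features lower in both, targeted genes left out, had a median of -0.22 in Dnmt1 cKO. Camera with an estimated correlation did not call them there (adjusted p = 0.136). Nor did it call them for Dnmt1 minus DN (-0.16) or Dnmt1 minus Np95 (-0.19, adjusted p = 0.278 for both).

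3 features outside the rule for named genes were chosen after their values were seen. 4933409K07Rik stood at 14.8 ± 1.63 and 1006 ± 960 FPKM in the Dnmt1 line (195 to 2076 FPKM in the 4 treated libraries), 8.33 and 15.2 FPKM in the Np95 line, 21.6 and 111 FPKM in the DN line, 16.1 and 4044 FPKM in the SN line and 29.4 and 6969 FPKM in the SD line. It was called in Dnmt1 cKO (log2 change 5.24, adjusted p = 0.00844), SN cDKO (7.84) and SD cDKO (7.82) by limma. The Dnmt1 call was lost with close pairs averaged (4.71, adjusted p = 0.0551) and without either untreated library, and the SD call with only these 4 libraries in the fit (adjusted p = 0.0724). Dnmt1_cKO 2 and 3, a close pair, stood at 1558 and 2076 FPKM and Dnmt1_cKO 1 and 4 at 195 and 196. Gm4262 rose in the same lines by 4.80, 7.58 and 8.06 and A430078G23Rik by 4.67, 7.94 and 9.0. Neither passed in DN cDKO, with log2 values of 2.24 and 2.60, nor in Np95 cKO. Zfp575 had log2 values of 2.05 in DN cDKO and 0.06 in Np95 cKO, neither called.

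**Figure D4:**
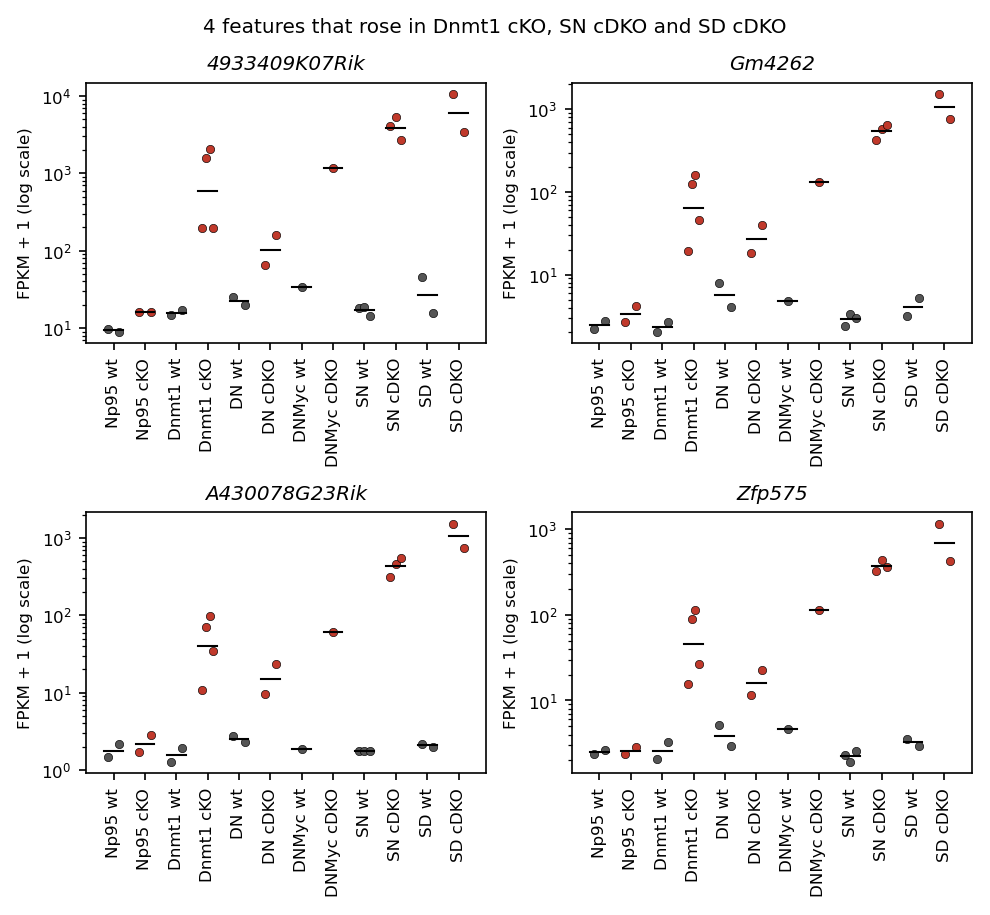
FPKM + 1 on a log scale of 4933409K07Rik, Gm4262, A430078G23Rik and Zfp575 in each of the 26 libraries (points; grey untreated, red at day 6 of 4-OHT), with the geometric mean of each group as a line. The arithmetic mean of 4933409K07Rik was 6969 FPKM in SD cDKO and 15.2 FPKM in Np95 cKO (8.33 FPKM untreated).

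Effects were also compared between lines directly, by a limma test of the difference. Removing Setdb1 in addition to Dnmt1 (SD effect minus Dnmt1 effect) gave 955 features, 220 higher and 735 lower, with Cd209c (difference 6.17), Rbmy1a1 (4.55) and Gabrr1 (3.91) highest among the named genes and Nanog (-4.91), Fgf4 (-4.70) and Ooep (-4.43) lowest. The pluripotency list differed by a median of -1.75, with 18 members lower and 27 adjusted over the list alone (camera adjusted p = 1.73e-09, adjusted p = 0.402 with an estimated correlation). Removing Setdb1 in addition to Np95 (SN effect minus Np95 effect) gave 626 features, 301 higher and 325 lower, and 1874 with the replicate block. Cd209c (7.99), Rbmy1a1 (7.37) and Zfp575 (7.32) differed upward and Fgf4 (-3.58), Tcl1 (-3.56) and Nanog (-3.42) downward. Genes of the 2-cell stage differed by a median of 2.09 (12 of 17 called, 15 adjusted over the list alone; camera adjusted p = 2.86e-15, adjusted p = 0.261 with an estimated correlation) and pluripotency genes by -1.47 (camera adjusted p = 1.02e-07, adjusted p = 0.526 with an estimated correlation). The count of 955 was 507, 371, 271 and 394 without Dnmt1_wt 1, Dnmt1_wt 2, SD_wt 1 or SD_cDKO 2. The count of 626 was 114, 224, 203 and 117 without Np95_wt 1, Np95_wt 2, Np95_cKO 1 or Np95_cKO 2, and 332, 307 and 951 without SN_wt 1, 2 or 3.

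SD and SN effects differed in 9 features, 4 higher and 5 lower, with 554 at an unadjusted p under 0.05. Dnmt1 (-2.85, adjusted p = 0.00189) was lower as targeted in SD alone, Mybpc3, a muscle sarcomere protein, was higher (2.85), and Defb8 (-2.17) and Klk1b24 (-1.5) were lower. Genes of the 2-cell stage differed by a median of -1.68, 15 of 17 lower adjusted over the list alone and 0 over all features, with medians in SN and SD of 2.12 and 1.52 in the S059 libraries and 2.01 and -0.47 in the others. For the 2-cell list camera gave an adjusted p of 6.07e-21, and adjusted p = 0.179 with an estimated correlation. Interferon response genes differed by -0.89, with medians in SN and SD of 0.12 and 0.04 in the S059 libraries and 1.54 and 0.24 in the others, and feeder markers differed by -0.64 (6 of 37 above 0). For the interferon list camera gave an adjusted p of 6.38e-10, and adjusted p = 0.348 with an estimated correlation. Dnmt1 and DN effects differed in 1 feature, Snord91a (223 at an unadjusted p under 0.05). Dnmt1 and Np95 effects differed in 2, the targets Uhrf1 (2.59) and Dnmt1 (-3.18), and DN and Np95 effects in 2, Snord91a and Dnmt1 (-2.62). The last did not pass without any 1 of its 8 libraries, and Uhrf1 not without 6 of its 10. The count of 9 was 41, 14, 16 and 60 without SD_wt 2, SD_cDKO 1, SD_cDKO 2 or SN_cDKO 3. Before treatment, 19 features differed among the 5 lines (530 at an unadjusted p under 0.05), and 7 (without Np95_wt 1) to 38 (without SN_wt 3) when 1 untreated library was left out.

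The DN line with Myc-tagged NP95 had 1 untreated and 1 treated library, so its differences have no replicate check and were not tested. Dnmt1 stood at 38.5 FPKM untreated and 6.97 FPKM at day 6, Uhrf1 at 66.0 and 90.3 FPKM and Setdb1 at 21.1 and 21.7 FPKM. Among the named features with the largest ratios, Zfp575 was at 3.58 and 112 FPKM, Gkn1, a stomach mucosa protein, at 0.594 and 21.2 FPKM, Ccl2, a chemokine, at 1.30 and 19.2 FPKM and Xlr4a at 0.410 and 9.64 FPKM. Gkn2 was listed at 0 and at 44.3 FPKM. On the lower side were Amn (38.5 and 6.85 FPKM), Ndufa4l2 (110.4 and 24.7 FPKM) and the 2-cell gene Zscan4c (9.29 and 1.25 FPKM). 4933409K07Rik, Gm4262 and A430078G23Rik stood at 32.9 and 1188, 3.78 and 133, and 0.868 and 60.2 FPKM. Ratios of FPKM + 1 were over 2-fold up in 378 of 13660 features and over 2-fold down in 153. The 41 features that rose in Dnmt1 cKO had a median log2 ratio of 0.70, above all of 10000 random lists matched on expression, and the 9 that fell had -0.48, at percentile 0.04. Rhox genes had a median of 0.44 (percentile 99.99), pluripotency genes 0.30 (100) and feeder markers 0.66 (100), while 2-cell genes (-0.55), germline genes (-0.22, percentile 0.01) and p53 targets (-0.17, percentile 0.07) lay at the low end. Most lists lay near an end, histone (0.05) and ribosomal protein genes (0.2) among them. Random lists ignore that members of a list can move together, so these percentiles do not measure chance.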

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

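Tests chosen only after the result was seen were those of the library series, of feeder carry-over and 4-OHT exposure alone for the pluripotency genes, and the other splits of the SN libraries; feeder carry-over for the third pattern was added late, with its prediction written before its value was computed. Differences between lines passed the limma test of the difference itself, as log2 values of the first effect minus the second. Dnmt1 and DN effects differed in 1 feature, Snord91a (-8.84), Dnmt1 and Np95 effects in 2, Uhrf1 (2.59) and Dnmt1 (-3.18), and DN and Np95 effects in 2, Snord91a (8.84) and Dnmt1 (-2.62). Snord91a was listed at 0 in every library except the 2 of DN cDKO, so its fitted values depend on the pseudocount and are no measured folds. SD and Dnmt1 effects differed in 955 features, among them Cd209c (6.17), Rbmy1a1 (4.55), Gabrr1 (3.91), Nanog (-4.91), Fgf4 (-4.70) and Ooep (-4.43), and in the pluripotency list (-1.75). SN and Np95 effects differed in 626 features, among them Cd209c (7.99), Rbmy1a1 (7.37), Zfp575 (7.32), Fgf4 (-3.58), Tcl1 (-3.56) and Nanog (-3.42), and in the 2-cell (2.09) and pluripotency lists (-1.47). SD and SN effects differed in 9 features, among them Dnmt1 (-2.85), Mybpc3 (2.85), Defb8 (-2.17) and Klk1b24 (-1.5), and in the 2-cell (-1.68) and interferon lists (-0.89). None of these list differences was called with an estimated correlation (adjusted p = 0.402, 0.261, 0.526, 0.179 and 0.348 in the order given). Among the 4 Dnmt1 cKO libraries, Taf7l at 4.26 FPKM in Dnmt1_cKO 1 lay far from the other 3; chance sets 1 library apart in about 1 in 20 such groups.

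The largest increases shared by SN and SD cDKO may in part come from transcripts that begin in or run through repeated sequence, since Setdb1 silences proviruses. The 12 features with log2 changes of 5 or more in both lines include Cd209c, Zfp575, Psg23, Bckdhb and Krt8. Of the 10 with a reference transcript, 7 held repeated 31-mers (24.9% of all 12274 features do), with a median over the 10 of 4.40% of 31-mers (90th percentile of all, 1.28%), a median that 0 of 10000 random sets of 10 reached, while Krt8, Bckdhb and 4930519F09Rik held none. A 31-mer shared within a gene family counts in the same way, and the random sets were not matched on length or gene type. The share therefore does not tell proviral from other repeated sequence. The lowest median of the 12 in any library series of either line was 6.80. They were chosen for large changes over both series together, so this median cannot test a difference between library series. Open remain fragments assigned to these genes from copies elsewhere and transcripts driven by a provirus, which the table cannot separate.

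The fall of pluripotency genes in SN and SD cDKO was set against 3 technical explanations. Carry-over of feeder fibroblasts needs the fall to fade where feeder markers changed least, but in the S059 pairs the highest median was -2.02. A shift in the scale of FPKM needs it to fade after median-of-ratios scaling, where the highest median was -1.37. Exposure to 4-OHT and Cre alone needs it in every line, but the lowest median in the Dnmt1, Np95 and DN lines was -0.17. Open remains RNA quality, which was not tested and of which ribosomal protein genes were fixed as a sign (medians -0.57 in SN and -1.22 in SD, lowest in the S059 libraries as well). Also open, as a hypothesis, is a loss of pluripotent identity or cells after deletion of Setdb1. Without a line with Setdb1 deleted alone, whether the second gene is needed cannot be told.

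The features higher in both SN and SD cDKO also lay higher in Dnmt1 cKO than in DN cDKO, by a median of 0.34 (adjusted p = 0.0154 with an estimated correlation), and so did feeder markers (1.5, 36 of 37 above 0) and primitive endoderm genes (2.12, 26 of 27). The shared features were chosen on SN and SD libraries alone, so by design selection on the Dnmt1 libraries does not apply, and the bound set for its test restates the pattern. Carry-over of feeder cells is a candidate source, since in the S059 pairs, where feeder markers differed by 0.06, the features differed by 0.087 (quartiles -0.06 and 0.29), against 0.54 in the other libraries with a feeder difference of 1.53; anything else that sets the series apart fits as well. Without Dnmt1_cKO 2 and 3, whose code ranges hold no untreated library of the Dnmt1 line, the median was 0.23 and still called (adjusted p = 0.0119 with an estimated correlation), so they are not the whole source, and their share in its size cannot be told apart from the deletion. The 1961 features lower in both SN and SD cDKO differed by a median of -0.16. They were not called by camera with an estimated correlation (adjusted p = 0.278), so the pattern was called for the rising features only. Long binding of NP95 at hemimethylated DNA, which the study's title raises, was not tested here, and clones differ between the lines.

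Of the 10 splits of the 6 SN libraries into 3 and 3, 1, the real one, gave as many calls (4202, against at most 0 in the others) and 1 gave as many list calls (13, against at most 10). The splits are too few for a share under 0.05. Every other split also mixes treated and untreated libraries in both groups, which widens the spread, so few calls there were likely from the start. With the preset correlation these mixed splits still called 6 to 10 lists. They also cut across the replicate numbers, which in the SN line are code ranges as well.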

How the results depend on the processing

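Alternatives chosen only after the data were seen were code range as a block, close pairs averaged, the 3 shallowest libraries left out, Dnmt1_cKO 2 and 3 left out, and small RNAs left out. Among single lists, scaling ended the calls of the epiblast list in SN (adjusted p = 0.0989), the feeder list in DN (0.0806) and the histone list in SD (0.187), and called the primitive endoderm list in Np95 (0.0354). The replicate block ended the call of the imprinted list in Dnmt1 (0.133) and called the epiblast list in SD (0.044), and medians not called in Np95 turned with scaling for the machinery (0.03 to -0.03) and pluripotency lists (0.04 to -0.02). Under the other settings, apart from the estimated correlation, list calls were only counted. Counts not named below stayed within 1.5 times. The results of single genes counted next leave out Dnmt1, Uhrf1 and Setdb1, whose lost calls are given below. Of the results of single genes (a gene in 2 comparisons counts as 2) 84 lost their call with only the compared groups in the fit, 30 without the 3 shallowest libraries, 28 with close pairs averaged, 19 with the replicate block, 16 without Dnmt1_cKO 2 and 3, 14 with the code range block, 12 with a pseudocount of 0.1, 9 without a filter and 2 each with the mean filter and with scaling; 115 were lost over the fits with 1 library left out. Where a setting has fewer libraries or features, that alone can end a call; for the other changes the cause was not tested. Depth limits the precision of low values in SN_wt 1, SN_cDKO 1 and Dnmt1_cKO 2 most.

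Counts of calls that moved over 1.5 times are given by setting. With a pseudocount of 0.1 they were 1 in Np95, 4 for SD minus SN and 12 at baseline, and the Myc-line medians were 0.81 and -0.89. Without a filter they were 17 in Np95, 7 in DN, 5 for Dnmt1 minus Np95, 5 for DN minus Np95 and 48 for SD minus SN. With mean FPKM of 1 or more they were 1 in Np95 and 5 for SD minus SN, with Myc-line medians of 0.68 and -0.56. With median-of-ratios scaling they were 1 for DN minus Np95 and 15 for SD minus SN, Dnmt1 in DN minus Np95 was -2.57 (adjusted p = 0.0909), and the Myc-line medians were 0.64 and -0.52. With the replicate block (pairing by number) they were 89 in Dnmt1, 1 in Np95, 3 for Dnmt1 minus DN, 2017 for SD minus Dnmt1 and 1874 for SN minus Np95. SN gave 5727 and SD 5691. In the Dnmt1 line this block leaves Dnmt1_cKO 3 and 4 without a partner and pairs Dnmt1_wt 2 across code ranges. The S059 covariate gave 141 in Dnmt1, 10 in Np95, 1581 for SD minus Dnmt1, 1506 for SN minus Np95 and 55 at baseline. A log2 change of at least 1 left 2245 in SN. An estimated correlation left 0 list calls in Dnmt1, 1 in Np95, 1 in DN, 0 in SN and 0 in SD.

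With only the compared groups in the fit the counts were 0 in Dnmt1, 0 in Np95, 2435 in SN, 26 in SD, 3 for Dnmt1 minus DN, 0 for Dnmt1 minus Np95, 4 for DN minus Np95, 50 for SD minus Dnmt1 and 4 for SD minus SN. Group means fix the log2 changes in that fit, so only the calls can move. Calls were lost for Dnmt1 -3.05 in Dnmt1 (adjusted p = 0.24), Uhrf1 -2.93 in Np95 (0.545), and Dnmt1 -2.49 and Uhrf1 -2.44 in DN (0.0933). In SD they were lost for Dnmt1 -3.08 (0.0558), Setdb1 -2.45 (0.0724) and Uhrf1 -1.42 (0.0786), which was not targeted there. The targeted genes of the SN line kept their calls. Among differences, calls were lost for Uhrf1 2.59 and Dnmt1 -3.18 for Dnmt1 minus Np95 (0.912). The same held for Dnmt1 -2.62 for DN minus Np95 (0.203) and Dnmt1 -2.85 for SD minus SN (0.053).

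Code range as a block gave 100 in Dnmt1, 1 in Np95, 6775 in SN, 6822 in SD, 3 for Dnmt1 minus DN, 3396 for SD minus Dnmt1, 3094 for SN minus Np95 and 15 for SD minus SN, and Uhrf1 in Dnmt1 turned to 0.15. Close pairs averaged gave 9 in Dnmt1, 3 in Np95, 2334 in SN, 1 for DN minus Np95, 198 for SN minus Np95 and 7 at baseline, with Dnmt1 -2.62 in DN minus Np95 (0.0961). Without the 3 shallowest libraries the counts were 8 in Dnmt1, 3 in Np95, 2485 in SN, 1 for DN minus Np95, 220 for SN minus Np95, 5 for SD minus SN and 6 at baseline, with Dnmt1 -2.62 in DN minus Np95 (0.0794). Without Dnmt1_cKO 2 and 3 they were 17 in Dnmt1 and 2 for Dnmt1 minus DN, and Uhrf1 in Dnmt1 turned to 0.15. Without small RNAs they were 0 for Dnmt1 minus DN and 0 for DN minus Np95, where Dnmt1 was -2.62 (0.056).

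Leaving out 1 library at a time, with a lone library assumed to vary like the other groups, gave these ranges of counts: 5 to 207 in Dnmt1, 1 to 2 in Np95, 3 to 6 in DN, 2934 to 3882 in SN, 2407 to 4029 in SD, 1 to 2 for Dnmt1 minus DN, 1 to 4 for Dnmt1 minus Np95, 1 to 2 for DN minus Np95, 271 to 1321 for SD minus Dnmt1, 114 to 951 for SN minus Np95, 6 to 60 for SD minus SN and 7 to 38 at baseline. Dnmt1 in DN minus Np95 (-2.82 to -2.41) lost its call in all 8 fits (adjusted p = 0.0674 to 0.377) and Uhrf1 in Dnmt1 minus Np95 (2.33 to 2.85) in 6 of 10 (0.0513 to 0.484). Values not called that changed sign ranged in Np95 from -0.077 to 0.33 for Dnmt1, -0.068 to 0.65 for A430078G23Rik, -0.089 to 0.20 for Zfp575 and -0.036 to 0.14 for Erv3, and in DN from -0.014 to 0.11 for Erv3. List calls ranged from 8 to 11 in Dnmt1, 6 to 8 in Np95, 5 to 8 in DN, 12 to 14 in SN and 10 to 13 in SD.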

Other observations

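No hypothesis was tested in this part, and the features and Mir675 were chosen after their values were seen. The DN line with Myc-tagged NP95 is set here beside the DN line without the tag, as values of 1 library per condition in the former and means of 2 in the latter. 4933409K07Rik was 32.9 FPKM untreated and 1188 FPKM at day 6 in that line, against 21.6 and 111 FPKM in the DN line without the tag. Gm4262 stood at 3.78 and 133 FPKM against 4.99 and 27.9 FPKM, and A430078G23Rik at 0.868 and 60.2 FPKM against 1.51 and 15.7 FPKM. Zfp575 stood at 3.58 and 112 FPKM against 3.03 and 16 FPKM. Dnmt1 was low in both treated states (6.97 and 8.75 FPKM) and Uhrf1 high with the tag (90.3 FPKM) and low without it (10.9 FPKM). Across features, log2 ratios of the tagged line correlated with the effects in Dnmt1 cKO at 0.27, DN cDKO at 0.12, Np95 cKO at 0.04, SN cDKO at 0.33 and SD cDKO at 0.34, and features are not independent replicates. The difference between the tagged and untagged lines was not tested, for want of replicates.

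The remaining lists of the tagged line had medians of 0.24 for imprinted genes (percentile 99.7 of random lists), 0.30 for trophectoderm genes (99.4), 0.20 for primitive endoderm genes (93.6), 0.47 for epiblast genes (99.95), 0.37 for interferon genes (99.99), -0.01 for proliferation genes (20.1), 0.22 for the machinery list (99.7), -0.10 for histone genes (0.05) and -0.27 for ribosomal protein genes (0.2).

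Mir675, which is made from H19, took values from 0 to 24547 FPKM across the 26 libraries.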
